A study of Mus musculus with 9 samples.

How the data were processed

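Retinas with the lens attached from E12.5 Vsx2 orJ/orJ mouse embryos were kept in culture for 24 h with 100 nM HX531 in 0.1% DMSO (n = 5) or with 0.1% DMSO alone (n = 4). EdU at 10 µM was present for the last 30 min, per the labels. RNA was extracted with Trizol, poly(A) RNA was selected, and libraries were made with a directional (strand-marking) kit, per the labels' protocols. The authors deposited raw read counts per gene, 1 file per library, and the submitters' processing notes name bcl2fastq, FastQC, Trim Galore, STAR and HTSeq with the mouse build GRCm38 (mm10). Their versions, the annotation release, the strand setting and any filters are not given in the sources used here. The values were whole numbers for 53715 versioned Ensembl gene identifiers, followed by HTSeq's categories of reads given to no gene. Those categories took 22.2% to 29.4% of all counts per library and were left out of library sizes and tests.

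Gene symbols, positions and exon overlaps were taken from GENCODE M21 for GRCm38. Of the identifiers, 53620 were found there without the version number and 51464 with it, and 95 had no symbol. Of 449 genes whose exons lie wholly inside exons of a gene on the other strand, 7 had at least 1 count over the 9 libraries and 4 had at least 100. Reads from such places appear to have been set aside as ambiguous, as counting without strand does, so values of genes with overlapping neighbours are uncertain. Reads with more than 1 place in the genome were not counted, which lowers genes with near-identical copies.

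Total counts in genes per library were, for HX531 replicates 1 to 5, 50226258, 31827630, 45180475, 37284077 and 40720617, and for vehicle replicates 1 to 4, 37270567, 37685294, 50163828 and 54287959. No pair of libraries of 1 group agreed within sampling noise (chi-square per degree of freedom 17.2 to 171), so none was a repeat deposit. The common biological coefficient of variation was 0.299.

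The groups came from the sample titles. Before the data were examined, the test, the samples, the gene lists, a panel of 27 genes, the alternatives and the rule for named genes were fixed. HX531 was compared with vehicle by edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr with a minimum count of 10, robust estimation, group as the 1 term and Benjamini-Hochberg adjustment at 0.05. This left 19314 genes. Standard errors of log2 changes were the size of the change divided by the square root of F. CPM values use TMM-scaled library sizes, and group values are means ± SD over libraries. The named genes were up to 12 per direction with the smallest adjusted p under 0.05, without predicted genes, clones and pseudogenes. Where fewer than 6 passed in a direction, the 6 with the smallest p were named. Up to 4 members of each called list, up to 2 of any other list described, and the panel were added.

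The 45 gene lists held 925 genes, of which 816 were tested at least once and 3 were not found. Lists with at least 5 tested members were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists. Camera was repeated with an estimated correlation per list, and fry was run for directional and mixed change. List scores were compared by an exact two-sided permutation test over all splits of the 9 libraries, whose smallest possible p is 0.00794. The same test was used for 6 measures of composition, namely the shares of crystallin, mitochondrial, haemoglobin, top 50 gene and unassigned counts and the mean level of Y chromosome genes.

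The alternatives were DESeq2 size factors, library size alone, no filter and a stricter filter on low counts (1 CPM in at least 4 libraries). Each library was left out in turn, the replicate number was added as a block, and each run of HX531 library numbers was set against all vehicle libraries. Lens marker and Y chromosome gene levels served as covariates, DESeq2 1.42.0 (Wald test) and limma-voom with sample quality weights replaced edgeR, and other thresholds were tried. Lens covariate and removal of HX531 replicate 2 together, the mean log2 CPM of macrophage markers as a covariate, and list member counts without that library, by DESeq2, by limma-voom and by unadjusted p, were added after the data were seen. The test was checked on simulated data for HX531 against vehicle with 19314 genes. Of these, 200 were changed by a known fold, all drawn from genes at a mean of 1 CPM or more, and the members of 1 list were shifted as well. The test recovered 32.8% of 67 genes changed by 1.5-fold, 67.2% of 67 changed by 2-fold and 97.0% of 66 changed by 4-fold, all with the right sign, and called 4 unchanged genes. Recovery of genes under 1 CPM was not checked. The list shifted by −0.5 was called by camera (adjusted p = 6.16e-16), and 0 of 43 unshifted lists were called. The simulated genes were drawn independently of each other, so this does not check lists whose members vary together. In the real data the estimated correlation between members reached 0.942, in the ribosomal list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.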

Results

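Retinas with the lens attached were taken from E12.5 mouse embryos homozygous for orJ. The orJ allele is a loss-of-function mutation of Vsx2, a homeobox gene that retinal progenitors need for growth and for keeping their retinal identity. The tissue was cultured for 24 h with 100 nM HX531, an antagonist of the retinoid X receptors (RXRs), or with the 0.1% DMSO vehicle, and poly(A) RNA was sequenced. There were 5 HX531 libraries and 4 vehicle libraries, which the labels number as replicates without naming embryos, litters or days, so the p-values measure the spread between these samples. RXRs act as partners of other nuclear receptors, among them the retinoic acid receptors (RARs), the oxysterol-sensing liver X receptors (LXRs) and the PPARs. The comparison asks which transcripts of the mutant retina depend on RXR signalling. Each library held between 31827630 and 54287959 counts in genes, and 19314 genes had enough counts to be tested.

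Of the 9 libraries, 8 resembled each other closely, with correlations of log2 normalised read counts (CPM, scaled to library size) between 0.969 and 0.986 across genes. HX531 replicate 2 stood apart, with correlations of 0.921 to 0.931 to the others. It had at least 1 count in 19806 genes, against 25341 to 26857 in the other libraries. Mitochondrially encoded transcripts made up 4.46% of its counts in genes, against 2.17% to 2.47% elsewhere. The first principal component (50.1% of the variance) separated this library from all others rather than HX531 from vehicle. It was kept in the test, and the counts of genes, of called lists and of changed members of called lists that differed without it are given as well. Lens content also varied, and crystallin genes took 0.0433% to 1.43% of the counts in the HX531 libraries and 0.129% to 1.64% in the vehicle libraries. The crystallin share averaged 0.420% ± 0.584 (SD, n = 5) with HX531 and 0.755% ± 0.725 (SD, n = 4) with vehicle, a difference smaller than the spread (exact two-sided permutation test, p = 0.437). Xist and the Y chromosome genes showed 5 female libraries (3 with HX531, 2 with vehicle) and 4 male libraries (2 with each). None of the 6 shares and scores of this kind differed between the groups after Benjamini-Hochberg adjustment. The lowest exact permutation p was 0.0873 (adjusted p = 0.524), for the share of counts assigned to no gene.

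**Figure D1:**
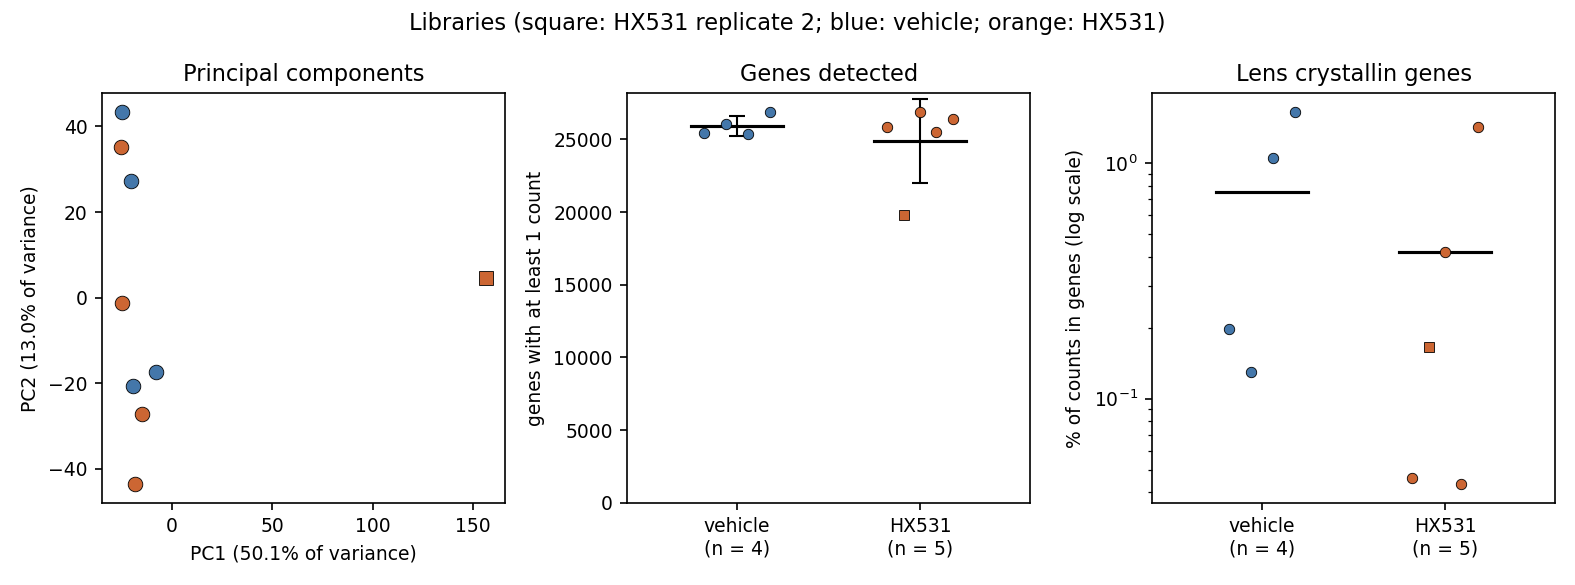
Each point is 1 library (vehicle, blue, n = 4; HX531, orange, n = 5; the square is HX531 replicate 2), placed by its first 2 principal components, by the number of genes with at least 1 count and by the percent of counts in lens crystallin genes on a log axis; horizontal lines are group means and bars are SD (no bars on the log axis). HX531 replicate 2 lies alone on the first component and has 19806 genes with a count, while the crystallin share spans 0.0433% to 1.64% within overlapping groups.

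HX531 lowered 16 genes, among them genes of lipid transport and lipid synthesis, and raised 4. Abca1, the cholesterol efflux transporter, showed the strongest evidence and fell 18.9-fold, from 103 ± 20.9 CPM (SD, n = 4) to 5.48 ± 1.29 CPM (SD, n = 5). Abcg1, its partner in cholesterol efflux, fell 9.67-fold, from 15.7 ± 2.57 to 1.64 ± 1.09 CPM. Dhrs3, which reduces retinaldehyde to retinol and is induced by retinoic acid, fell 5.22-fold, from 22.7 ± 7.30 to 4.36 ± 0.807 CPM. Srebf1, which encodes the regulator of fatty acid synthesis SREBP-1, fell 1.84-fold, and Scd2, a stearoyl-CoA desaturase, fell 2.43-fold. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 20 of the 19314 genes passed an adjusted p of 0.05, 16 lower and 4 higher with HX531. At an unadjusted p under 0.05 there were 794 genes, 431 higher and 363 lower. The median log2 change of all tested genes was 0.0049.

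**Figure D2:**
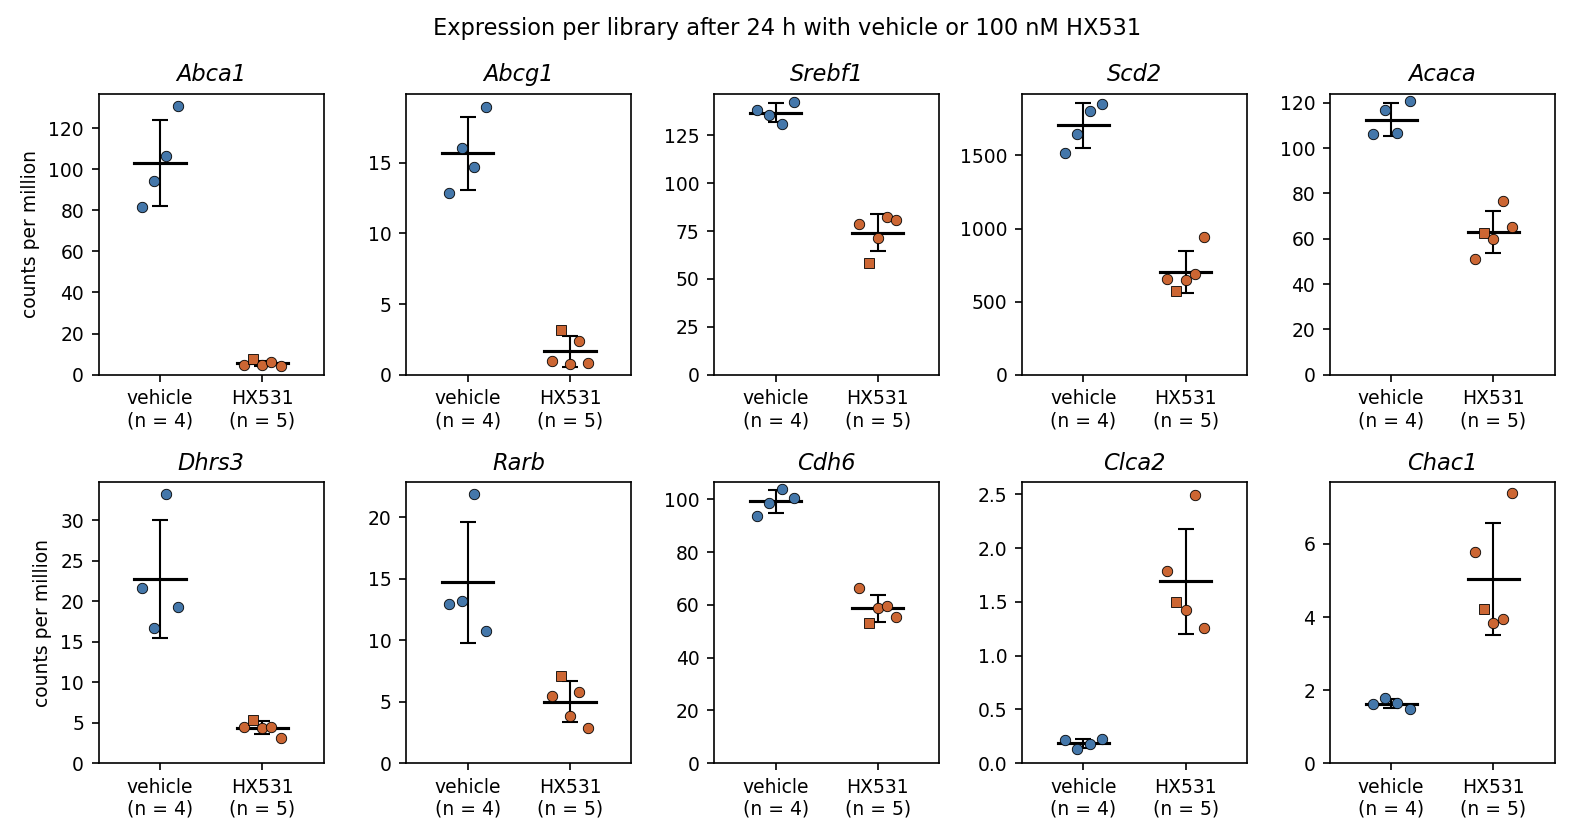
Expression in CPM on linear axes from 0 for 10 genes in each library (vehicle, blue, n = 4; HX531, orange, n = 5; the square is HX531 replicate 2), with group means (lines) and SD (bars). Abca1 fell from a mean of 103 to 5.48 CPM and Dhrs3 from 22.7 to 4.36 CPM with no overlap between the groups, while Rarb also did not overlap but did not pass the adjustment over all genes.

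The log2 changes of the genes that fell were, with their standard errors, −4.24 ± 0.19 for Abca1, −3.27 ± 0.42 for Abcg1, −2.38 ± 0.22 for Dhrs3, −1.28 ± 0.13 for Scd2 and −0.88 ± 0.09 for Srebf1. Their adjusted p values in edgeR's test were 5.28e-06, 0.0206, 0.00231, 0.0038 and 0.0038. In the GRCm38 assembly, Abca1 (ENSMUSG00000015243.4) lies on chromosome 4 from 53030787 to 53159895 and Dhrs3 (ENSMUSG00000066026.14) on chromosome 4 from 144892827 to 144928209. Abcg1 (ENSMUSG00000024030.6) lies on chromosome 17 from 31057675 to 31117988, and Srebf1 (ENSMUSG00000020538.15) on chromosome 11 from 60199089 to 60222581. All 4 are protein-coding genes, and the counts are over annotated exons. Further lipid genes that fell were Acaca, the first committed enzyme of fatty acid synthesis (−0.84 ± 0.10, edgeR adjusted p = 0.0102), and Acsl3, an acyl-CoA synthetase (−0.71 ± 0.07, adjusted p = 0.00231). Rnf145, a ubiquitin ligase of sterol metabolism, fell too (−0.78 ± 0.08, edgeR adjusted p = 0.00231). The remaining fallers named by the fixed rule were Cdh6, a cadherin (−0.76 ± 0.07), Tmem132e (−0.92 ± 0.11), Etl4 (−0.73 ± 0.09) and Bcam, a laminin-binding cell adhesion protein (−0.50 ± 0.07). For these 4 genes edgeR's adjusted p lay between 0.00231 and 0.0206. A further 4 genes fell and lay outside the naming rule, so they are named after their values were seen. They were Ccl6, a chemokine of myeloid cells (−3.22 ± 0.47), Dio3os, a noncoding RNA next to the Dio3 gene (−1.18 ± 0.17), Bdh1, a ketone body enzyme (−0.63 ± 0.09), and Map3k5, a stress-activated kinase (−0.57 ± 0.09). Ccl6 was low throughout, at 1.57 ± 0.538 CPM with vehicle (SD, n = 4) and 0.167 ± 0.0750 CPM with HX531 (SD, n = 5). Exons on the other strand overlap 13.7% of the exonic bases of Bdh1.

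The 4 genes that rose were Clca2 (3.15 ± 0.37, adjusted p = 0.00785), Klf11, a Krüppel-like transcription factor (0.64 ± 0.09, adjusted p = 0.0206), Chac1, a glutathione-degrading enzyme of the stress response (1.63 ± 0.24, adjusted p = 0.0342), and Slc7a3, a cationic amino acid transporter (1.40 ± 0.21, adjusted p = 0.0345), all by edgeR. Clca2 was low throughout, at 0.187 ± 0.0419 CPM with vehicle (SD, n = 4) and 1.69 ± 0.490 CPM with HX531 (SD, n = 5). The next higher genes by unadjusted p did not pass. Mmrn1 had a log2 change of 3.24 ± 0.57 (edgeR adjusted p = 0.101) and Sema3g one of 1.34 ± 0.24 (adjusted p = 0.103). In all 20 genes that passed, every HX531 library lay on the same side of every vehicle library. Such separation was seen in 408 genes, or 2.11% of those tested, and chance gives 1.59% for 5 libraries against 4.

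Without HX531 replicate 2, the library that stood apart, 31 genes passed (7 higher, 24 lower), and the 20 genes above were all among them. The count depended on other libraries too. It was 10 without HX531 replicate 1, 9 without HX531 replicate 3, 12 without HX531 replicate 5, and 10, 12, 11 and 10 without vehicle replicates 1, 2, 3 and 4 in turn. Abca1, Dhrs3, Cdh6, Rnf145, Acsl3, Scd2, Srebf1, Tmem132e and Clca2 passed whichever library was left out, and the other 11 genes lost the call without at least 1 library. In the library titles, the vehicle libraries carried numbers 17, 18, 27 and 28. By these numbers, HX531 replicates 1 to 3 (numbers 4 to 6) and HX531 replicates 4 and 5 (numbers 20 and 21) formed separate runs, which held no vehicle library. Against all vehicle libraries the first set gave 10 genes, all lower, and the second set 5 genes, all lower. Abca1, Srebf1, Acsl3 and Rnf145 were among the genes that passed in both.

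Of 45 gene lists, 13 were called by camera, 6 higher and 7 lower with HX531, and 1 kept the call with an estimated correlation. Camera called 16 of the 44 lists it could test without HX531 replicate 2, the same 13, with the ribosomal list in the opposite direction, and 3 more. Of 100 splits of the 9 libraries, the real one included, 22 gave as many called lists, so chance cannot be excluded for this count. The 19 tested LXR targets gave the clearest shift. Of these, 5 fell (Abca1, Abcg1, Scd2, Srebf1 and Acaca), 14 did not pass, and 17 of the 19 log2 changes were below 0. Adjusted over the list alone, 11 were lower, and DESeq2 called 8 and limma-voom 7 over all genes. The median log2 change was −0.43, and the list was lower by camera (adjusted p = 7.78e-20; adjusted p = 0.000929 with an estimated correlation). The list score, the mean centred log2 CPM of the members, lay between −0.44 and −0.24 in the HX531 libraries and between 0.40 and 0.55 in the vehicle libraries. The exact two-sided permutation p of that difference was 0.00794, the smallest that splits of 9 libraries into 5 and 4 can give, and 0.119 after adjustment over the 45 lists. Without HX531 replicate 2, 7 members fell, and 14 were lower adjusted over the list alone. This list was the 1 that kept its call with an estimated correlation. Its median was −0.44 with HX531 replicates 4 and 5 alone against vehicle and −0.49 with HX531 replicates 1 to 3.

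Genes of fatty acid synthesis, which SREBP proteins control, were called lower as a list by camera, though not with an estimated correlation. In the fatty acid list of 18 tested genes, 3 fell (Scd2, Srebf1 and Acaca), 15 did not pass, and 6 were lower adjusted over the list alone. DESeq2 and limma-voom called 4 each over all genes. Fasn, the fatty acid synthase, had a log2 change of −0.60 ± 0.09 and narrowly did not pass over all genes (edgeR adjusted p = 0.0503). The list was lower by camera (adjusted p = 0.000163; adjusted p = 0.461 with an estimated correlation), with a median log2 change of −0.06, and the exact permutation p of its scores was 0.0635. The list's 3 fallers were all among the 7 genes it shared with the LXR list, whose median was −0.60, while the other 11 fatty acid genes had a median of 0.07 and none passed. Without HX531 replicate 2 the list median was −0.0007, 4 members fell, and adjusted over the list alone 7 were lower and 1 was higher. The median was −0.13 without HX531 replicate 5. Leaving out vehicle replicates 1, 2 and 4 in turn gave −0.11, −0.14 and −0.03. The call ended with HX531 replicates 4 and 5 alone against vehicle (camera adjusted p = 0.226).

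Genes of cholesterol synthesis, also under SREBP control, were called higher as a list by camera, though not with an estimated correlation. It held 25 tested genes, of which none passed over all genes and 22 had log2 changes above 0. Adjusted over the list alone, 3 were higher, namely Insig1, a sterol-regulated retention protein of the SREBP pathway, Ldlr, the LDL receptor, and Pcsk9, which promotes degradation of that receptor. Their log2 changes were 0.34 ± 0.07, 0.36 ± 0.10 and 0.98 ± 0.29. Fdps, a prenyl diphosphate synthase, had a log2 change of 0.54 ± 0.17 and did not pass either adjustment. The list was higher by camera (adjusted p = 6.37e-06; adjusted p = 0.235 with an estimated correlation), with a median of 0.12. All HX531 list scores lay above all vehicle scores (exact permutation p = 0.00794, the smallest possible, and 0.119 after adjustment). At an unadjusted p under 0.05 in edgeR's test 5 members counted, by DESeq2 and by limma-voom 1 each passed after adjustment, and without HX531 replicate 2 there was 1, Insig1, with 7 members higher adjusted over the list alone.

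**Figure D3:**
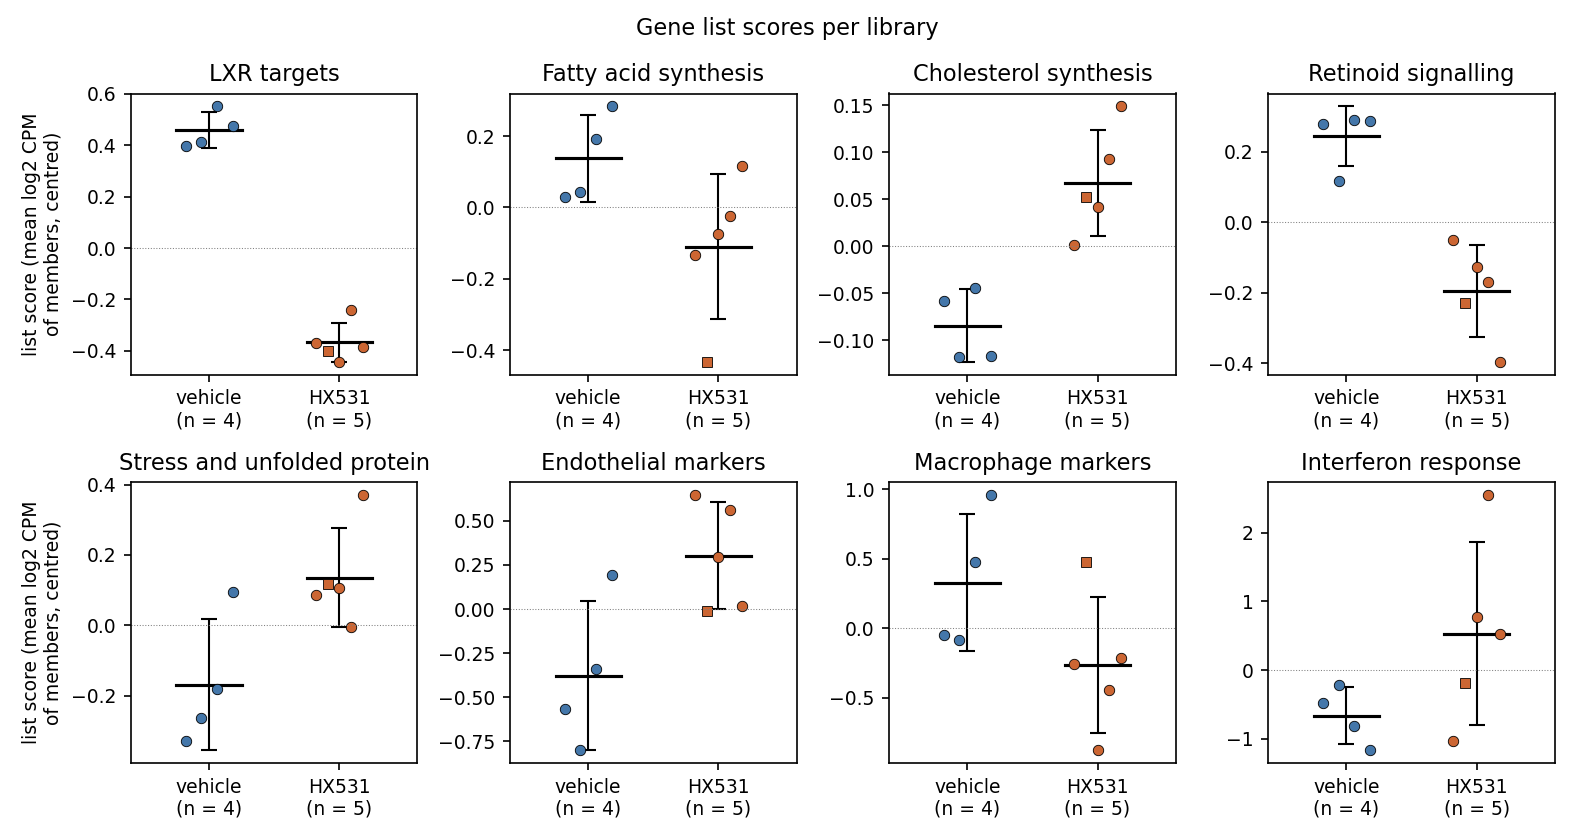
List scores (mean over tested members of log2 CPM, each gene centred on its mean of the 9 libraries) for 8 gene lists, 1 point per library (vehicle, blue, n = 4; HX531, orange, n = 5; the square is HX531 replicate 2), with group means (lines) and SD (bars); the dotted line marks 0. LXR target scores lie between −0.44 and −0.24 with HX531 and between 0.40 and 0.55 with vehicle, whereas interferon scores spread from −1.02 to 2.55 among the HX531 libraries.

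The retinoid signalling list, which holds RAR and RXR targets and enzymes of retinoid metabolism, was called lower by camera, though not with an estimated correlation. Of 24 tested genes 1 fell (Dhrs3), 23 did not pass, and 5 were lower adjusted over the list alone. In edgeR's test 6 had an unadjusted p under 0.05, and DESeq2 called 4 and limma-voom 5 after adjustment. The members nearest to passing were Rarb, a retinoic acid receptor that retinoic acid induces (−1.55 ± 0.28), Lrat, which esterifies retinol (−3.05 ± 0.65), and Cyp26b1, which degrades retinoic acid (−2.67 ± 0.62). Their edgeR adjusted p values over all genes were 0.107, 0.273 and 0.404. Lrat was low throughout, at 1.14 ± 0.414 CPM with vehicle (SD, n = 4) and 0.131 ± 0.0984 CPM with HX531 (SD, n = 5). Rarb went from 14.7 ± 4.93 CPM (SD, n = 4) to 5.01 ± 1.66 CPM (SD, n = 5). Genes on the other strand overlap 38.4% of its exonic bases, and the strand setting of the counting is not given in the sources used here, so its level is uncertain. Cyp26a1, another retinoic acid hydroxylase, had a log2 change of −0.40 ± 0.38 that was about its error (edgeR adjusted p = 1.00). The list was lower by camera (adjusted p = 0.00209; adjusted p = 0.316 with an estimated correlation), with a median log2 change of −0.14, and its scores did not overlap between groups (exact permutation p = 0.00794, and 0.119 after adjustment). The median was −0.06 without vehicle replicate 3, and the call ended with HX531 replicates 1 to 3 alone against vehicle (camera adjusted p = 0.12). Without HX531 replicate 2, 3 members fell in edgeR's test, Cyp26b1 (adjusted p = 0.00172) and Lrat (adjusted p = 0.0352) in addition to Dhrs3, and 6 were lower adjusted over the list alone. Over all alternatives edgeR's or DESeq2's adjusted p ran from 0.000878 to 1.00 for Cyp26b1 and from 0.00049 to 1.00 for Lrat. The receptors themselves were measured at similar levels. Log2 changes were −0.03 ± 0.09 for Rxra, 0.03 ± 0.06 for Rxrb and −0.16 ± 0.16 for Rxrg, none of which passed (edgeR adjusted p = 1.00 for each).

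None of the 26 tested PPAR targets passed over all genes or adjusted over the list alone, and their median log2 change was −0.01 (camera adjusted p = 0.447). At an unadjusted p under 0.05 edgeR counted 4, and DESeq2 and limma-voom called 0 each. The smallest p values among them belonged to Slc25a20 (0.23 ± 0.08) and Ucp2 (0.43 ± 0.17), both above 0. Angptl4, a PPAR target of the fixed panel, had a log2 change of 0.47 ± 0.31, and of 0.20 without HX531 replicate 2. Among 10 tested thyroid hormone and vitamin D targets, none passed over all genes in edgeR's test and 3 were lower adjusted over the list alone. DESeq2 called 3 and limma-voom 1, and 5 had an unadjusted p under 0.05 in edgeR. The list included Dio3, a thyroid hormone-inactivating deiodinase (−1.07 ± 0.18, edgeR adjusted p = 0.0949 over all genes), and Hr, a corepressor (−1.62 ± 0.33, adjusted p = 0.202). Camera did not call the list (adjusted p = 0.123).

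The list of integrated stress response and unfolded protein response genes was called higher by camera, though not with an estimated correlation. Of 29 tested genes 2 rose (Chac1 and Slc7a3), 27 did not pass, and adjusted over the list alone 7 were higher and 1 was lower. DESeq2 called 4 and limma-voom 3 over all genes. Asns, asparagine synthetase (0.70 ± 0.13, edgeR adjusted p = 0.113), and Psat1, a serine synthesis enzyme (0.55 ± 0.11, adjusted p = 0.238), were among the 7, the lower member was the cystine transporter Slc7a11, and 25 of the 29 changes were above 0. The list was higher by camera (adjusted p = 3.55e-09; adjusted p = 0.101 with an estimated correlation) and by fry's directional test (adjusted p = 0.0462), with a median of 0.18. The exact permutation p of its scores was 0.0397 (0.357 after adjustment), and vehicle replicate 4 scored above HX531 replicates 1 and 4. Adjusted over the list alone, 10 members were higher and 1 was lower without HX531 replicate 2.

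Lists of endothelial and of macrophage markers were called by camera as well, though not with an estimated correlation. No single member passed over all genes in edgeR's test. All 18 tested endothelial markers had log2 changes above 0, with a median of 0.74, and 9 were higher adjusted over the list alone (7 without HX531 replicate 2). At an unadjusted p under 0.05 edgeR counted 10, DESeq2 called 2 and limma-voom 0. Ptprb, a vascular phosphatase (1.86 ± 0.37), Flt1, a VEGF receptor (1.20 ± 0.27), Pecam1 (0.78 ± 0.24) and Tie1 (0.94 ± 0.29) led the list. Camera called it higher (adjusted p = 2.27e-11; adjusted p = 0.316 with an estimated correlation), and the exact permutation p of the scores was 0.0397 (0.357 after adjustment). Mmrn1 and Sema3g are also expressed in endothelium, but they were named above for ranking first among higher genes that did not pass. Their direction was fixed by that choice and adds no evidence to this list. Macrophage and microglia markers had a median log2 change of −0.55 over 20 tested genes, 17 of them below 0, and none was lower adjusted over the list alone. Leaving out HX531 replicate 2 gave a median of −0.73 and 5 lower members adjusted over the list alone. In edgeR's test 7 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each. Fcgr3, an Fc receptor (−1.42 ± 0.39), Cx3cr1, the fractalkine receptor (−1.06 ± 0.30), Hexb (−0.27 ± 0.09) and Trem2 (−1.40 ± 0.49) led that list, and exons on the other strand overlap 32.3% of those of Hexb. Camera called it lower (adjusted p = 4.86e-07; adjusted p = 0.467 with an estimated correlation), and the exact permutation p of the scores was 0.111. The myeloid chemokine Ccl6 and the LXR targets, several of which macrophages express, moved in the same direction as these markers. Both were singled out because they were lower, so this is no separate evidence of fewer macrophages.

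Interferon response genes were called higher as a list by camera, though not with an estimated correlation. Their levels differed widely among the HX531 libraries. All 23 tested genes had log2 changes above 0, with a median of 1.66, yet none passed over all genes or adjusted over the list alone. By edgeR 12 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each. Oas1a (3.04 ± 0.92), Isg15 (3.06 ± 1.09), Ifitm3 (1.92 ± 0.68) and Ifi27 (1.52 ± 0.48) had the smallest p values. Isg15 averaged 8.18 ± 11.6 CPM with HX531 (SD, n = 5) and 0.987 ± 0.606 CPM with vehicle (SD, n = 4). Camera called the list higher (adjusted p = 1.68e-10; adjusted p = 0.467 with an estimated correlation). The scores of the HX531 libraries ran from −1.02 to 2.55 and those of the vehicle libraries from −1.17 to −0.21 (exact permutation p = 0.119). Scores of 4 of the 5 HX531 libraries lay above every vehicle score. The highest score was that of HX531 replicate 4, and without it the median was 0.85.

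Genes that define the retina itself did not change detectably. Vsx2 transcripts were at 627 ± 82.0 CPM with vehicle (SD, n = 4) and 616 ± 83.8 CPM with HX531 (SD, n = 5). Log2 changes of eye field and progenitor genes were −0.03 ± 0.12 for Vsx2, 0.07 ± 0.09 for Pax6, 0.01 ± 0.13 for Rax, −0.03 ± 0.13 for Sox2 and 0.20 ± 0.13 for Ccnd1. Mitf (−0.05 ± 0.15) and Otx2 (−0.19 ± 0.26), which pigment epithelium expresses, stayed within their errors. The Notch pathway genes Notch1 (0.01 ± 0.11), Hes1 (−0.21 ± 0.09) and Hes5 (−0.21 ± 0.89) did not pass. Neurogenic and neuronal genes were expressed at low levels. Log2 changes were 0.18 ± 1.00 for Atoh7, 0.31 ± 0.59 for Neurog2, −0.29 ± 0.52 for Ascl1, −0.29 ± 0.33 for Isl1, −0.27 ± 0.20 for Tubb3 and 0.78 ± 0.47 for Crx. Exons on the other strand overlap 27.4% of the exonic bases of Rax, 23.4% of those of Ccnd1 and 31.8% of those of Hes5. Pou4f2, a ganglion cell factor, had 0 to 13 counts per library and was not tested. For all of these panel genes edgeR's adjusted p was 1.00. The errors leave room for changes of more than 1 log2 unit of Atoh7, Neurog2, Ascl1, Hes5 and Crx.

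The corresponding lists were not called. Camera did not call retinal progenitor genes (24 tested, median 0.02, adjusted p = 0.552), neurogenic precursor genes (26 tested, median 0.07, adjusted p = 0.523) or ganglion cell genes (23 tested, median −0.09, adjusted p = 0.333). Nor did camera call pigment epithelium and melanin genes (28 tested, median −0.15, adjusted p = 0.16), Notch pathway genes (23 tested, median 0.04, adjusted p = 0.4) or ciliary margin genes (18 tested, median 0.02, adjusted p = 0.879). No member of these 6 lists passed over all genes in edgeR's test, and at an unadjusted p under 0.05 they held 3, 0, 1, 3, 1 and 1 genes in the order given. DESeq2 called 1 progenitor gene and 1 pigment epithelium gene, and limma-voom the latter 1. Adjusted over the list alone, 1 progenitor gene was higher, Slc1a3, a glutamate transporter (0.56 ± 0.12, edgeR adjusted p = 0.273 over all genes), and 1 pigment epithelium gene was lower, Lrat, which passed over all genes without HX531 replicate 2.

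Mitosis genes had a median log2 change of −0.11, with 27 of 30 tested genes below 0 and none lower adjusted over the list alone or at an unadjusted p under 0.05 in edgeR's test. DESeq2 and limma-voom called 0 each. Ccna2 (−0.15 ± 0.07), Kif11 (−0.16 ± 0.08), Tpx2 (−0.17 ± 0.08) and Cenpf (−0.14 ± 0.07) had the smallest p values. Camera called the list lower (adjusted p = 0.000333; adjusted p = 0.803 with an estimated correlation), and lost it without vehicle replicate 1 (median −0.08) or vehicle replicate 2 (median −0.06). DNA replication genes (31 tested) had a median of −0.01 and were not called by camera (adjusted p = 0.904).

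Another 4 lists were called by camera without a member that passed over all genes or adjusted over the list alone, and none kept the call with an estimated correlation. At an unadjusted p under 0.05 in edgeR's test they held 0 lens, 0 ribosomal, 3 BMP and TGF-beta and 1 NRF2 genes, and DESeq2 and limma-voom called 0 in each. Lens markers were lower (27 tested, median −0.74; adjusted p = 0.0036; adjusted p = 0.803 with an estimated correlation), led by Crygb (−2.17 ± 1.26), Cryba4 (−1.89 ± 1.20), Crygf (−1.81 ± 1.25) and Crygd (−1.61 ± 1.18). That call ended without vehicle replicate 4 (median −0.04), vehicle replicate 3 (−0.48), HX531 replicate 1 (−0.50) or HX531 replicate 4 (−0.47), and the median was −2.12 without HX531 replicate 5. Cytosolic ribosomal protein genes were higher (50 tested, median 0.16; adjusted p = 0.00595; adjusted p = 0.803 with an estimated correlation), with Rpl37 (0.35 ± 0.27), Rpl38 (0.30 ± 0.24), Rps28 (0.30 ± 0.23) and Rpl35 (0.23 ± 0.20) first. Camera called them lower without HX531 replicate 2 (median −0.04, adjusted p = 0.0466), and the call ended without vehicle replicate 2 (0.11) or vehicle replicate 4 (0.14). The ribosomal median was 0.25 without HX531 replicate 4. Gamma crystallin and ribosomal protein genes have near-identical copies, so their individual levels are uncertain, as is that of Rpl35, of whose exonic bases 66.2% are overlapped on the other strand.

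BMP and TGF-beta targets were higher (15 tested, median 0.21; adjusted p = 0.017; adjusted p = 0.467 with an estimated correlation), led by Ccn2 (0.45 ± 0.20), Skil (0.12 ± 0.05), Smad7 (0.34 ± 0.15) and Tgfbi (0.71 ± 0.37). That call ended without HX531 replicate 5 (median 0.21), vehicle replicate 2 (0.15) or vehicle replicate 3 (0.14), and without HX531 replicate 2 the median was 0.13 and 1 member was higher adjusted over the list alone. NRF2 and oxidative stress genes were lower (18 tested, median −0.09; adjusted p = 0.0335; adjusted p = 0.467 with an estimated correlation), led by Slc7a11, the cystine transporter (−0.57 ± 0.15), Osgin1 (−0.65 ± 0.30), Hmox1 (−0.51 ± 0.26) and Cat (−0.13 ± 0.08). The NRF2 call ended without HX531 replicate 1 (median −0.05), HX531 replicate 4 (−0.03), vehicle replicate 3 (−0.07) or vehicle replicate 4 (−0.03).

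The remaining lists were not called by camera, among them photoreceptor precursor genes (median −0.02, adjusted p = 0.901), oxidative phosphorylation genes (median 0.01, adjusted p = 0.271), p53 targets (median 0.04, adjusted p = 0.648) and hypoxia and glycolysis genes (median 0.03, adjusted p = 0.861). Adjusted over the list alone, Cyp1a1 was higher and Abcc3 lower among 9 tested xenobiotic response genes (log2 changes of 1.86 ± 0.37 and −0.77 ± 0.25), and mt-Nd6 (−0.39 ± 0.08) and mt-Nd5 (−0.38 ± 0.08) were lower among 7 mitochondrially encoded genes. None of these 4 genes passed over all genes in edgeR's test, while DESeq2 called 1 xenobiotic and 2 mitochondrial genes and limma-voom 0 and 2. Lists of other tissues, namely periocular mesenchyme, surface epithelium, erythroid cells, muscle and Schwann cells, held no member that passed either adjustment. Across all 32 lists that camera did not call, its adjusted p ran from 0.123 to 0.929. It called 3 of them lower without HX531 replicate 2, namely oxidative phosphorylation genes (median −0.12, adjusted p = 6.68e-10), heat shock genes (median −0.05, adjusted p = 0.0216) and mitochondrially encoded genes (median −0.14, adjusted p = 0.0387, 3 members lower adjusted over the list alone).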

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

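The tests of the treatment as a source of the HX531 replicate 2 pattern, of library numbers, fewer macrophages and SREBP activity for the LXR pattern, and both tests for the interferon pattern were chosen after the result was seen. Of 210 groups of values examined, 13 held a library far from the rest of its group, and chance gives about 1 in 20. Of these, 8 were in HX531 replicate 2. The next values below are those of the same group.

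In HX531 replicate 2 the number of genes with a count was 19806 (next lowest 25504), and the unassigned share was 29.4% (next highest 23.6%). Its mitochondrial share was 4.46% (2.40%), its haemoglobin share 0.0472% (0.00996%) and the share of the top 50 genes 14.1% (9.87%). Cyp26b1 was at 0 CPM (next 0.611), Rpl38 at 129 CPM (next 72.0) and Angptl4 at 11.8 CPM (next 6.32). In other libraries, Slc7a11 was at 61.9 CPM in vehicle replicate 3 (next 41.3) and Tubb3 at 5.85 CPM there (next 9.13). Tmem132e was at 20.8 CPM in HX531 replicate 1 (next 26.1), the retinoid list score was 0.116 in vehicle replicate 2 (next 0.279), and the crystallin share was 1.43% in HX531 replicate 5 (next 0.42%).

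HX531 replicate 2 had fewer detected genes and a separate place on the first principal component. Lower depth is argued against, since the other 8 libraries thinned to its total count still held at least 24859 genes with a count. For the treatment, the other 4 HX531 libraries lay −1.59% of its distance from the vehicle mean on that component, on the far side. The component mainly reflects HX531 replicate 2, and its place was known when the test was chosen. The test thus does not decide about the treatment. The values show only that the other 4 HX531 libraries did not share the place of HX531 replicate 2. Few RNA molecules at the start may be the source. Of 13763 genes at a mean of 2 CPM or more elsewhere, 31 had no count in it, against at most 2 in any other library.

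LXR targets were lower with HX531. Lens content as the whole source is argued against by a median of −0.48 with the lens covariate. The fall was not confined to library numbers 4 to 6, since the median was −0.44 with HX531 replicates 4 and 5 alone. Those 2 libraries, numbers 20 and 21, form a run without a vehicle library as well. Library number and treatment therefore cannot be told apart. With the macrophage marker level as a covariate the median was −0.51. Macrophage scores overlapped between the groups while LXR scores did not, and both were known when this test was chosen. It thus does not decide about fewer macrophages. The value shows only that the LXR list stayed lower with that covariate in the fit. Lower SREBP activity as a whole was tested with the cholesterol synthesis score. That score was higher by 0.15 with HX531 (exact permutation p = 0.00794, and 0.119 after adjustment). Camera with an estimated correlation did not call the list (adjusted p = 0.235), and no member passed over all genes. The score was known when the test was chosen, so the test does not decide about SREBP activity. The values show only that the cholesterol synthesis list was not lower in these libraries. A direct effect of RXR antagonism on LXR targets remains a hypothesis found on these same data, and none of these tests separates it from an indirect effect.

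Interferon response genes were higher in part of the HX531 libraries. The exact permutation p of the score was 0.119, so the treatment and chance cannot be told apart with 9 libraries. Without HX531 replicate 4 the median was 0.85 with an exact permutation p of 0.171, which leaves open that this library made much of the difference. Both criteria replaced earlier ones after their outcome was known. The first had counted against the treatment a lowest HX531 score of −1.02, below the vehicle median of −0.64, and against replicate 4 alone a camera adjusted p of 1.31e-06 without it, but 1 library excludes nothing and camera's preset ignores the correlation within this list.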

How the results depend on the processing

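The fit with the lens covariate and without HX531 replicate 2, the fit with the macrophage covariate, and list member counts without HX531 replicate 2, by other tools or by unadjusted p were chosen after the result was seen. The other alternatives were planned. Of the 20 genes that passed, all kept their direction in all 420 values, and 281 of these still passed. The count of 20 ran from 9 to 31 when 1 library was left out, was 5 with HX531 replicates 4 and 5 and 10 with HX531 replicates 1 to 3, 16 with the macrophage covariate, 88 by DESeq2 and 47 by limma-voom (all 20 shared with each), and 794 at an unadjusted p under 0.05. Fewer samples may account for part of the losses, but their cause was not tested, and leaving out HX531 replicate 2 raised the count to 31. With the replicate block the count was 2. The numbers do not pair the libraries (r of deviations 0.138, −0.062, 0.0017 and −0.218 for numbers 1 to 4), and HX531 replicate 5 has no partner. Camera called 16 lists without HX531 replicate 2. Of the 13 lists called, 1 was left with an estimated correlation and 2 by fry's directional test. Fry's mixed test, which takes change in either direction, called 9 of the 45 lists. Among these were lists that camera did not call, namely thyroid hormone and vitamin D targets (fry mixed adjusted p = 0.000624), xenobiotic genes (0.000681) and mitochondrially encoded genes (0.0207). Lists kept their call in 227 of 286 values, were weaker in 54 and reversed in 5. With the macrophage covariate these were lens markers, at 0.786, and macrophage markers by camera's direction, at −0.0587, neither of them called. The covariate is made from the latter, and the cause for the former was not tested. The other reversed list was the ribosomal one, at −0.0443 without HX531 replicate 2, −0.183 with HX531 replicates 4 and 5, and −0.0460 with the lens covariate and without HX531 replicate 2. Over left-out libraries it ran from −0.0443 to 0.253, and the cause was not tested. Of 123 named genes that did not pass, 37 of 2569 values passed and 24 genes changed sign at least once. The 6 composition measures passed in 0 of 10 alternatives, with a lowest exact permutation p between 0.0286 and 0.375. At this depth and n, changes of 1.5-fold in genes at a mean of 1 CPM or more were mostly missed in simulated data.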

Other observations

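The test of LXR against PPAR targets was chosen after the result was seen, and the tests of macrophage markers and of other splits were planned.

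Of 100 splits of the 9 libraries into 5 and 4, the real one included, 2 called as many genes as the 20 of the real split. Such a count was uncommon among the splits, but chance is not excluded for the count of genes. The other split called 54 genes and the next 6. It put HX531 replicates 1, 2 and 4 with vehicle replicates 1 and 2, the 5 libraries with a crystallin share of 0.198% or less, against 4 with 0.42% or more. This split follows lens content, but among the vehicle libraries it also parts library numbers 17 and 18 from 27 and 28. Lens content and library number cannot be told apart there. Among the HX531 libraries it does not follow the runs of numbers (4, 5 and 20 against 6 and 21). With the lens covariate, 14 genes passed for HX531 against vehicle. For the 13 called lists, 22 of 100 splits gave as many (highest other 17), so chance could not be excluded for the count of lists.

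A hypothesis that targets of RXR partner receptors respond alike to HX531 was tested with the LXR and PPAR lists. The LXR minus PPAR score differed by −0.90 between HX531 and vehicle on the log2 scale (exact permutation p = 0.00794, the smallest possible). Both scores were known when the test was chosen, and the LXR gap between groups exceeded the whole spread of the PPAR scores. The outcome was thus fixed in advance. The values show that these lists did not shift alike in these libraries, and the test does not decide the hypothesis.

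Fewer macrophages in the HX531 libraries may account for the lower macrophage markers, and would lower all such markers alike. Mrc1 minus the mean of C1qa, C1qb and C1qc differed by −0.53 between groups (exact permutation p = 0.437), which decides neither way. Macrophage markers had a median of 11.2 CPM with vehicle (highest 37.5), endothelial markers 3.04 CPM (highest 25.6), and lens markers 75.9 CPM (highest 3326). Y chromosome genes in HX531 replicate 2, a library with high Xist, summed to 2.40% of the male mean, against at most 0.271% in the other female libraries.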
